A study of Canis lupus familiaris with 8 samples.

How the data were processed

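Total RNA from dog alveolar bone was measured on 8 Affymetrix whole-transcript arrays, which report a summarised brightness for each probe set, a group of short probes against the same transcript. The values used are those the authors deposited, with 22708 probe sets in each array. They were treated as log2 values: none lay below 0, the highest was 14.5, and the array medians lay between 6.25 and 6.31. The deposited log2 values were taken as already normalized between arrays because of these medians. The summarisation, background correction, normalization and base of the logarithm are not given in the sources used here, so every fold stated rests on base 2. Arrays have no sequencing depth. Their number, 2 per group, limits the precision, and no detection p-value or background signal was used here. A value near the low end of an array has no known distance from background.

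The groups came from the sample titles: C, D2, D6 and DT6, with 2 arrays each. The digit in a title was read as weeks after surgery, since the treatment protocol in the labels lists observations at 0, 2, 4 and 6 weeks. The labels do not say which animal gave which array. The p-values of single genes therefore measure only the spread between these arrays, which may be technical.

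Of the probe sets, 16545 had 1 gene symbol in the platform annotation, 370 had several and 5793 were not listed with a gene. Symbols were checked by gene identifier against a RefSeq gene table of the assembly UU_Cfam_GSD_1.0. Of the 16545 probe sets, 15820 had an identifier in that table, and 0 symbols changed. A genome build is not named with the values, so no coordinates are given. Probe sets with several symbols or none were left out of the comparisons. For the 516 genes with more than 1 probe set, the one with the highest mean over all 8 arrays was kept, which left 15947 genes. No filter on dim genes was applied.

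Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit on the 4 group means and eBayes with a variance trend. All 8 arrays entered 1 fit, so the groups shared an estimate of the spread with 4 residual degrees of freedom. The tests were two-sided, with Benjamini-Hochberg adjustment over the 15947 genes in each of 5 comparisons and a threshold of 0.05 on the adjusted p. Log2 differences are given with limma's moderated standard error (SE), for 2 arrays against 2. "Rose" and "fell" are used only of genes or lists past the threshold.

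A set of 30 gene lists was fixed from textbook knowledge before the data were examined. Each was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 150 tests of lists and comparisons. The same test with a correlation estimated from the residuals, and limma's fry, were run as alternatives. An adjusted p "with an estimated correlation" refers to the former. The camera test sets the members of a list against the other genes, so its p-values do not measure the spread between arrays alone. The estimated correlation ran from −0.18 for the osteocyte list to 0.77 for the oral epithelium list, and was 0.54 for the interferon list. Where it lies above the preset 0.01, the preset p-values are too small. For 24 of the 150 tests the median, mean and test differed in sign, and 0 of those 24 passed the threshold. A further 2 lists, of motile cilium and of columnar epithelium genes, were written after airway genes had been seen among the largest changes, from members whose values had not been looked at.

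Genes were named by a rule fixed together with the lists. In each comparison it takes the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap. From each list it takes up to 4 members past the threshold with the largest change or, where none passed, up to 2 with the largest difference, given as values. In any comparison it takes the members of a key list of bone, cartilage and cytokine genes: RUNX2, SP7, ALPL, BGLAP, IBSP, SPP1, COL1A1, SOST, DMP1, ACP5, CTSK, MMP9, MMP13, TNFSF11, TNFRSF11B, POSTN, COL3A1, COL2A1, ACAN, SOX9, BMP2, VEGFA, IL1B and IL6. Genes known only by a locus identifier count in the rule and may go unnamed.

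The gene test and the list test were tested on simulated data for DT6 against D6. Each of 20 runs had 15947 genes, of which 200 were changed. The spread of each gene was that already moderated by eBayes, and not the measured spread. At the threshold, 78% of the 2-fold and 99.4% of the 4-fold changes were recovered, and 6.71% of the calls were false. A comparison with no changed gene gave a mean of 0.35 calls. A list of 20 genes shifted by 0.5 log2 had an unadjusted p under 0.05 in 100% of runs, and so did 2.59% of unshifted lists. The simulated genes varied independently, so this does not test the lists under correlation between genes. It also held no differences in tissue between replicates, such as the oral epithelium transcripts of D2 array 2 and D6 array 1. Recovery in the real data may therefore be lower.

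The alternatives were no variance trend, robust eBayes, quantile normalization on top of the deposited values, median centring, the upper 75% or 50% of genes by mean, the mean of all probe sets of a gene, all probe sets tested, a fit of the compared groups alone, array weights, the replicate number as a block, other thresholds, and each array left out in turn. With an array left out, the lone array of its group is assumed to vary like the other groups. After the data had been seen, 2 more alternatives were added, 1 without the arrays rich in oral epithelium transcripts and 1 without the genes that follow the airway pattern. Intervals on list medians are 95% bootstrap intervals over members from 10000 draws. They measure the spread between genes of a list and not between arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.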

Results

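Alveolar bone is the part of the jaw that holds the tooth roots. The study measured gene expression in dog maxillary alveolar bone during healing of a surgical defect, and asked how moving a tooth into the healing site, as in orthodontic treatment, alters it. Group C was sound bone around premolar roots. Groups D2 and D6 were tissue regenerated in the defect with the bone beside it, at 2 and 6 weeks after surgery as the group names were read. Group DT6 was the same kind of tissue at 6 weeks with protraction, that is, forward movement, of a tooth. Each group had 2 arrays. The replicates correlated across genes with r of 0.983 in C, 0.986 in D2, 0.975 in D6 and 0.9745 in DT6. Values are log2 probe set values as deposited, and each difference is given as log2 ± SE for 2 arrays against 2.

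The comparison of D2 with C asks what differed between tissue 2 weeks after surgery and sound bone. Transcripts of dividing cells, of macrophages and of fibrillar matrix and collagen assembly were higher in D2, while osteocyte and adipocyte transcripts were lower. Of the 28 measured members of the proliferation list, 21 rose, or 23 adjusted over the list alone. TOP2A, the topoisomerase of dividing cells, rose by 2.34 ± 0.31 (adjusted p = 0.00356), KIF11, a mitotic motor, by 2.15 ± 0.26, and the cell cycle marker MKI67 by 2.01 ± 0.18, which is 4.03-fold. Of the 17 monocyte and macrophage genes, 11 rose, or 13 adjusted over the list alone. GPNMB, a glycoprotein of macrophages and osteoclasts, rose by 2.84 ± 0.18 (adjusted p = 0.000138), the NADPH oxidase subunit CYBB by 1.65 ± 0.38 and the complement receptor VSIG4 by 1.43 ± 0.26. The proliferation list had a median of 1.23 (adjusted p = 1.32e-17, camera) and the macrophage list 1.06 (adjusted p = 1.57e-09). Each had an adjusted p = 0.734 with an estimated correlation.

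In the fibrillar matrix and collagen assembly list 5 of 27 members rose, or 11 adjusted over the list alone, with a list median of 0.58 (adjusted p = 4.10e-06, and adjusted p = 0.736 with an estimated correlation). CTHRC1, a secreted protein of repair fibroblasts, rose by 1.68 ± 0.34, the proteoglycan BGN by 1.12 ± 0.22, and tenascin C, TNC, by 0.91 ± 0.24. Of 20 matrix proteases 7 rose, or 9 adjusted over the list alone, among them the macrophage elastase MMP12 by 3.31 ± 0.83, ADAMTS12 by 1.30 ± 0.20 and the collagenase MMP13 by 1.21 ± 0.26. Without D2 array 2, which is rich in oral epithelium transcripts, the MMP12 difference was 1.72 (adjusted p = 0.0845), and without C array 1 that of CTHRC1 was 1.03 (adjusted p = 0.032). The protease list median was 0.69 (adjusted p = 0.000828, and adjusted p = 0.736 with an estimated correlation). Among cartilage genes, ACAN, the core protein of aggrecan, rose by 2.68 ± 0.40 and HAPLN1, which links aggrecan to hyaluronan, by 1.60 ± 0.38. MATN3, the cartilage matrix protein matrilin 3, fell by 4.92 ± 0.46 (adjusted p = 0.000678), the largest fall in the comparison, and MIA fell by 0.82 ± 0.17. Of the 21 cartilage genes 2 rose and 2 fell, or 3 and 3 adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.822).

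Genes of resident bone cells differed less evenly. In the osteocyte list of 6 genes MEPE, a matrix phosphoglycoprotein, fell by 2.29 ± 0.21 and SOST, the Wnt inhibitor sclerostin, by 1.33 ± 0.18, while PDPN rose by 1.36 ± 0.17. Adjusted over the list alone, 3 fell and 1 rose. The list median was −1.17 (adjusted p = 0.0297, and adjusted p = 0.734 with an estimated correlation), and without C array 1 its adjusted p was 0.0691. None of the 20 osteoblast and bone matrix genes passed the threshold in limma over all genes, and 3 rose and 2 fell adjusted over the list alone. ALPL, the alkaline phosphatase of mineralising cells, differed by 0.83 ± 0.33, IBSP by 1.09 ± 0.41, SP7 by 0.63 ± 0.26, COL1A1 by 0.52 ± 0.24, BGLAP by 0.24 ± 0.30 and RUNX2 by −0.43 ± 0.15. AMELX, the enamel protein amelogenin, fell by 2.91 ± 0.43. Of 16 osteoclast genes only 1 rose, also adjusted over the list alone: TCIRG1, a subunit of the acid-secreting proton pump, by 0.72 ± 0.17, while ACP5 at 1.07 ± 0.33 and MMP9 at 1.11 ± 0.36 did not pass. TNFRSF11B, the decoy receptor osteoprotegerin, differed by −0.89 ± 0.24 (adjusted p = 0.052).

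Adipocyte genes fell in 5 of 16 cases, or 7 adjusted over the list alone, with a list median of −0.78 (adjusted p = 0.00012, and adjusted p = 0.786 with an estimated correlation). The lipid droplet proteins PLIN4 and PLIN1 fell by 1.66 ± 0.30 and 1.46 ± 0.36, and leptin, LEP, by 1.35 ± 0.22. In the list of immediate early and mechanical response genes, EGR1 fell by 0.97 ± 0.20, NR4A1 by 0.90 ± 0.21 and EGR3 by 0.62 ± 0.15, and 4 of 22 fell adjusted over the list alone. That list had a median of −0.23 (adjusted p = 0.0196, and adjusted p = 0.786 with an estimated correlation), and its call ended without C array 1 (adjusted p = 0.125) or D2 array 1 (median −0.11, adjusted p = 0.174). Of 22 BMP and TGF-beta genes 2 fell, or 4 adjusted over the list alone: BMP3 by 1.42 ± 0.25 and BMP6 by 0.96 ± 0.16. Of 23 Wnt genes 3 fell and 1 rose, or 6 and 1 adjusted over the list alone. RSPO3 fell by 1.59 ± 0.31, FRZB by 1.49 ± 0.24 and DKK2 by 1.23 ± 0.30, while TNFRSF19 rose by 1.19 ± 0.21. These lists did not pass (adjusted p = 0.057 and 0.079). FGF2 fell by 1.20 ± 0.19, while IGF1 rose by 0.81 ± 0.13. Among vessel genes, FLT1 fell by 1.21 ± 0.19 and EMCN by 0.97 ± 0.19, while PLVAP rose by 0.82 ± 0.13. The chemokine CCL2 rose by 1.60 ± 0.31 and CXCL8 by 1.53 ± 0.40. Without D2 array 2 the CXCL8 difference was 0.81 (adjusted p = 0.196), and without C array 2 that of EGR1 was −0.65 (adjusted p = 0.0636).

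The largest rises in D2 were of genes of airway and gland epithelium. BPIFA1, a secreted protein of the upper airway, rose by 6.98 ± 0.54 (126-fold, adjusted p = 0.000365), from values of 4.37 and 5.52 in C to 12.60 and 11.25. TSPAN1 rose by 5.07 ± 0.26, AGR2, which helps fold mucins, by 5.01 ± 0.25, MUC13 by 4.84 ± 0.59, CLCA1 by 4.71 ± 0.62, BPIFB1 by 4.59 ± 0.76, the club cell protein SCGB1A1 by 4.47 ± 0.61, and PIGR, the receptor that carries IgA across epithelia, by 4.36 ± 0.34. The 2 members that rose in the granulocyte list were LTF, by 4.31 ± 0.38, and OLFM4, by 2.12 ± 0.34, which glands and mucosal epithelia also express. EPCAM, an epithelial adhesion molecule, rose by 2.54 ± 0.61. Of the 49 motile cilium genes, 15 rose, or 23 adjusted over the list alone, with a median of 0.40 (adjusted p = 0.0132 with an estimated correlation, over 10 tests of added lists). Of 27 columnar epithelium genes 2 rose, also 2 adjusted over the list alone, with a median of 0.26 (adjusted p = 0.00256, and adjusted p = 0.425 with an estimated correlation). Genes of stratified oral epithelium were unequal between the replicates: the 21 genes of that list averaged 2.10 log2 above C in D2 array 2 and 0.11 in D2 array 1.

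In all, 1339 of 15947 genes passed the threshold in D2 against C, of which 902 rose and 437 fell, and 56.3% of all genes had non-overlapping groups, where chance gives 33.3%. The count was 354 without C array 1, 724 without C array 2, 310 without D2 array 1 and 441 without D2 array 2. Of the 88 named genes that passed, 24 passed whichever array was left out, among them BPIFA1, AGR2, GPNMB, KIF11, MKI67, TOP2A, MATN3, MEPE, SOST and AMELX.

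**Figure D1:**
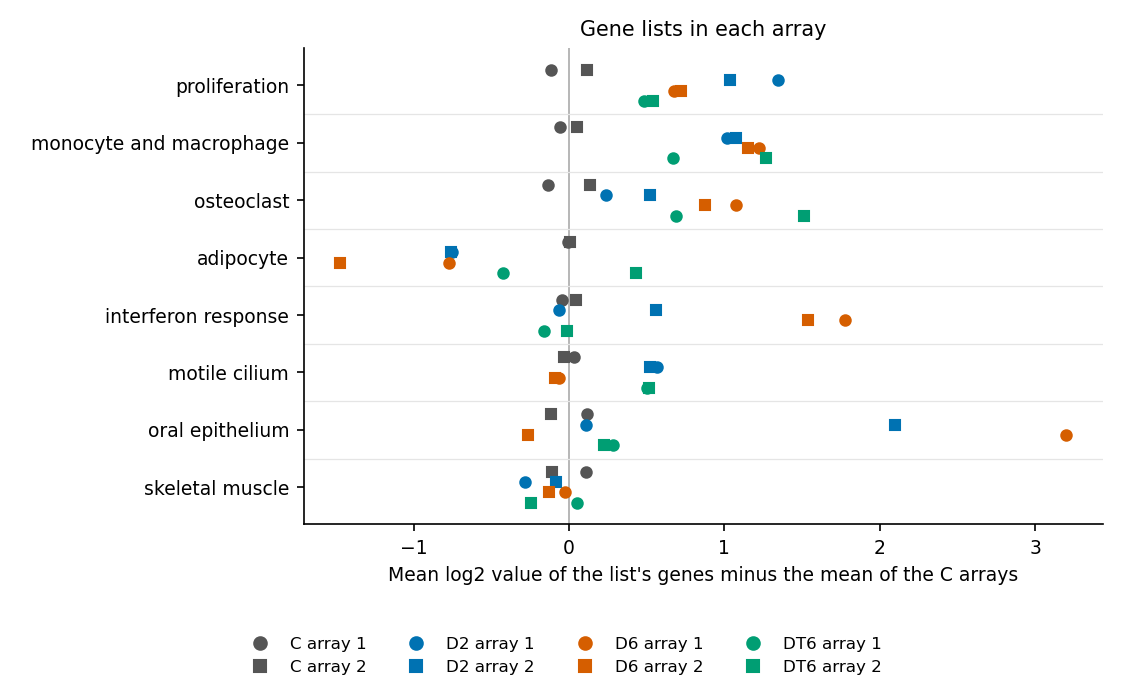
Each point is an array: the horizontal axis gives the mean log2 value of a list's genes minus the mean of the C arrays, each line across is 1 of 8 gene lists, colours are groups and symbols array numbers. Proliferation genes lie highest in D2 (1.34 and 1.03), interferon response genes in D6 (1.78 and 1.53), motile cilium genes in D2 and DT6, and oral epithelium genes in D2 array 2 (2.10) and D6 array 1 (3.20).

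The comparison of D6 with C asks what differed between tissue at 6 weeks and sound bone. Genes of osteoclasts and of macrophages, and those induced by interferon, were higher in D6, and adipocyte genes were lower. In the osteoclast list 3 of 16 genes rose, or 12 adjusted over the list alone. ACP5, the tartrate-resistant acid phosphatase that marks osteoclasts, rose by 2.07 ± 0.33 (4.19-fold, adjusted p = 0.0227), the gelatinase MMP9 by 2.40 ± 0.36 and TCIRG1 by 1.09 ± 0.17, while CTSK, the osteoclast collagenase cathepsin K, differed by 0.93 ± 0.26 and did not pass. These genes had a median of 0.89 (adjusted p = 1.46e-08, and adjusted p = 0.736 with an estimated correlation). Of the monocyte and macrophage genes 10 of 17 rose, or 15 adjusted over the list alone, with GPNMB at 2.31 ± 0.18, the Fc receptor chain FCER1G at 1.62 ± 0.25, CD68 at 1.60 ± 0.24 and the myeloid transcription factor SPI1 at 1.58 ± 0.21. Their median was 1.34 (adjusted p = 3.97e-15, and adjusted p = 0.734 with an estimated correlation).

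Interferon-induced genes rose in 13 of 17 cases, or 16 adjusted over the list alone, with a median of 1.67 (adjusted p = 9.99e-22, and adjusted p = 0.734 with an estimated correlation). The antiviral GTPases MX1 and MX2 rose by 2.80 ± 0.30 and 2.72 ± 0.27, and the oligoadenylate synthetases OAS1 and OAS2 by 2.32 ± 0.28 and 2.11 ± 0.18. The interferon-induced chemokine CXCL10 rose by 1.89 ± 0.33. Some of this was already present in D2: CXCL10 averaged 4.49 in C, 5.97 in D2 and 6.38 in D6, and MX2 6.47, 7.79 and 9.19. In D2 against C 1 of the 17 interferon genes rose, also 1 adjusted over the list alone. The list median there was 0.20 (adjusted p = 0.17, camera, and adjusted p = 0.947 with an estimated correlation). MX1 had values of 9.56 and 9.34 in D6, and 6.62 and 6.67 in C. Proliferation genes rose in 5 of 28 cases, or 16 adjusted over the list alone, with TOP2A at 1.60 ± 0.31 and MKI67 at 1.33 ± 0.18 and a median of 0.66 (adjusted p = 2.34e-12, and adjusted p = 0.734 with an estimated correlation). The lymphocyte genes CD2 and CD4 rose by 1.80 ± 0.28 and 1.27 ± 0.21.

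Adipocyte genes fell in 3 of 16 cases, or 11 adjusted over the list alone: PLIN1 by 1.91 ± 0.36, the triglyceride synthesis enzyme DGAT2 by 1.87 ± 0.38 and LEP by 1.13 ± 0.22. Over the list the median was −1.06 (adjusted p = 5.25e-10, and adjusted p = 0.736 with an estimated correlation). MATN3 fell by 3.85 ± 0.46, FMO2 by 3.47 ± 0.68, AMELX by 2.96 ± 0.43 and MEPE by 1.61 ± 0.21. CDH19, a cadherin of Schwann cells, fell by 1.98 ± 0.29 and was the only one of 13 nerve and Schwann cell genes to pass, or 3 adjusted over the list alone. The matrix proteases MMP9 and MMP13 rose, MMP13 by 2.10 ± 0.26, and were the only 2 of 20 to pass, or 9 risen and 1 fallen adjusted over the list alone. None of the 27 fibrillar matrix genes passed in limma, over all genes or over the list alone, and TNC differed by 0.92 ± 0.24 and BGN by 0.91 ± 0.22. None of the 22 immediate early genes passed over all genes, and 3 fell adjusted over the list alone. As lists, the proteases (median 0.50, adjusted p = 0.00107) and fibrillar matrix (median 0.44, adjusted p = 0.00211) rose, and the nerve (median −0.13, adjusted p = 0.0124) and immediate early lists (median −0.18, adjusted p = 0.0378) fell. With an estimated correlation the adjusted p was 0.736, 0.786, 0.734 and 0.827 for these 4. Without C array 1 the fibrillar matrix, nerve and immediate early calls ended (adjusted p = 0.112, 0.133 and 0.133). The fibrillar matrix median was then 0.25 and the immediate early median −0.12. The fibrillar matrix call also ended without D6 array 2 (median 0.25, adjusted p = 0.196), and the immediate early call without D6 array 1 (adjusted p = 0.0997), DT6 array 1 (adjusted p = 0.0564) or DT6 array 2 (adjusted p = 0.0583).

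Bone-forming genes did not pass: ALPL differed by 0.44 ± 0.33, IBSP by 1.22 ± 0.41, COL1A1 by 0.44 ± 0.24 and RUNX2 by −0.35 ± 0.15. SOST differed by −0.75 ± 0.18 (adjusted p = 0.074) and ACAN by 1.77 ± 0.40 (adjusted p = 0.065). None of the 21 oral epithelium genes passed in limma, over all genes or over the list alone, yet the list rose with a median of 1.60 (adjusted p = 0.00385, and adjusted p = 0.854 with an estimated correlation). DSG1, a desmosomal cadherin of stratified epithelium, was 9.87 in D6 array 1 and 4.23 in D6 array 2, against 3.82 and 3.80 in C. Without D6 array 1 the list median was −0.36, and without C array 2 the list's adjusted p was 0.0594. S100A8, made by granulocytes and keratinocytes alike, differed by 3.43 ± 1.59 (adjusted p = 0.33), with 10.13 in D6 array 1 and 4.17 in D6 array 2. None of the 49 motile cilium and 27 columnar epithelium genes passed in limma, over all genes or over the list alone, with medians of −0.07 (adjusted p = 0.137) and 0.10 (adjusted p = 0.338).

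In D6 against C 280 genes passed, 157 risen and 123 fallen, with 48.6% of all genes non-overlapping against 33.3% by chance. This count rested on single arrays more than any other. It was 0 in limma without C array 1, with 1986 genes at an unadjusted p under 0.05. It was 37 without C array 2, 10 without D6 array 1, 127 without D2 array 1 and 127 without D2 array 2, and it rose to 683 and 675 without DT6 arrays 1 and 2, which share in the estimate of the spread. Without both arrays rich in oral epithelium transcripts it was 49. None of the 46 named genes that passed did so whichever array was left out, since 0 passed without C array 1.

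**Figure D2:**
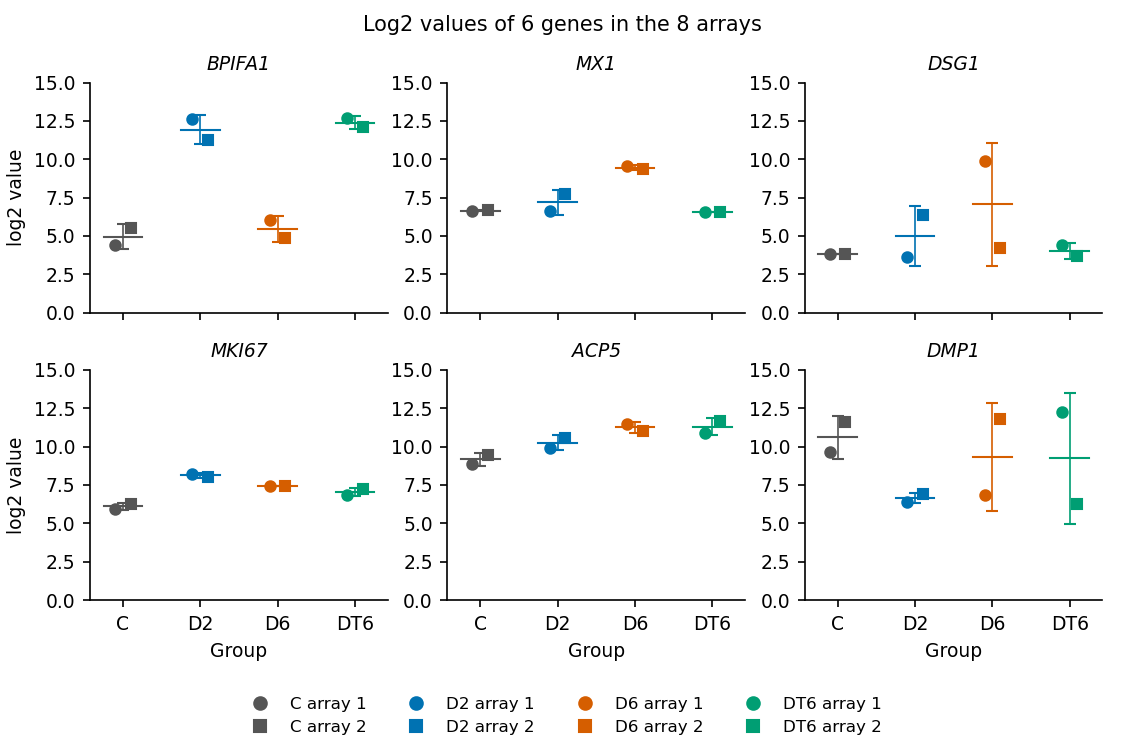
Log2 values (vertical axes) of 6 genes in the 4 groups: points are arrays, horizontal lines group means and bars the SD of 2 arrays. BPIFA1 is above 11 in the D2 and DT6 arrays and at most 6.04 in the others, MX1 is highest in both D6 arrays (9.56 and 9.34), and DSG1 and DMP1 differ between replicates.

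The comparison of DT6 with C asks what differed from sound bone where a tooth had been moved into the defect. Osteoclast and macrophage genes were again higher in the defect tissue, and airway epithelium genes showed the largest rises. ACP5 rose by 2.12 ± 0.33 (4.35-fold, adjusted p = 0.0125), MMP9 by 2.49 ± 0.36, TCIRG1 by 1.26 ± 0.17 and NFATC1, the transcription factor that drives osteoclast formation, by 0.86 ± 0.15. These were 4 of 16 osteoclast genes, or 12 adjusted over the list alone, and CTSK differed by 0.90 ± 0.26 without passing. The list median was 1.01 (adjusted p = 5.25e-10, and adjusted p = 0.736 with an estimated correlation). Of 17 monocyte and macrophage genes 6 rose, or 13 adjusted over the list alone, including CD68 by 1.86 ± 0.24, GPNMB by 1.72 ± 0.18 and CD14 by 1.69 ± 0.26, with a median of 0.93 (adjusted p = 1.27e-10, and adjusted p = 0.734 with an estimated correlation). MKI67 rose by 0.93 ± 0.18 and RRM2 by 1.08 ± 0.18, which were 2 of 28 proliferation genes, or 10 adjusted over the list alone. Their median was 0.46 (adjusted p = 1.27e-07, and adjusted p = 0.736 with an estimated correlation). Without DT6 array 2 the osteoclast median was 0.53 and the macrophage median 0.53, both still past the threshold.

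BPIFA1 rose by 7.44 ± 0.54 (174-fold), BPIFB1 by 5.26 ± 0.76, SCGB1A1 by 4.90 ± 0.61, DMBT1 by 4.83 ± 0.56, LTF by 4.69 ± 0.38, ALDH1A1 by 4.61 ± 0.29, TSPAN1 by 4.53 ± 0.26, AGR2 by 4.47 ± 0.25 and PIGR by 4.43 ± 0.34. Of the 49 motile cilium genes 10 rose, or 21 adjusted over the list alone, with a median of 0.45 (adjusted p = 0.0132 with an estimated correlation). None of the 27 columnar epithelium genes passed in limma over all genes, 1 rose adjusted over the list alone, and their median was 0.31 (adjusted p = 0.0202, and adjusted p = 0.508 with an estimated correlation). JCHAIN, which joins IgA units, differed by 2.18 ± 0.52 (adjusted p = 0.067), and EPCAM by 2.27 ± 0.61 (adjusted p = 0.093).

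MATN3 fell by 5.16 ± 0.46 (adjusted p = 0.000763) and AMELX by 2.82 ± 0.43. The Wnt antagonist DKK2 fell by 2.05 ± 0.30 and was the only one of 23 Wnt genes to pass, or 6 adjusted over the list alone. PIEZO2, a mechanically gated ion channel, fell by 2.26 ± 0.44, MSX2 by 1.58 ± 0.31, BMP6 by 0.72 ± 0.16 and FGF2 by 0.93 ± 0.19. BMP6 was the only one of 22 BMP and TGF-beta genes to pass, or 3 adjusted over the list alone. MMP13 rose by 2.07 ± 0.26, and with MMP9 made 2 of 20 matrix proteases, or 4 adjusted over the list alone. The vitamin D receptor VDR rose by 0.87 ± 0.16. As lists the matrix proteases rose (median 0.31, adjusted p = 0.0373), and Wnt signalling (median −0.30, adjusted p = 0.0136) and BMP and TGF-beta signalling (median −0.21, adjusted p = 0.0453) fell. With an estimated correlation the adjusted p was 0.750, 0.736 and 0.736 for these 3. The protease call ended without C array 1 (adjusted p = 0.0917), C array 2 (adjusted p = 0.0582) or DT6 array 1 (adjusted p = 0.0572), the Wnt call without C array 1 (adjusted p = 0.114) or DT6 array 2 (median −0.056, adjusted p = 0.0597), and the BMP call without C array 2 (adjusted p = 0.245) or DT6 array 2 (median −0.09, adjusted p = 0.126). With the replicate number as a block the BMP call also ended (adjusted p = 0.0519). No interferon list gene passed in limma, over all genes or over the list alone, and MX2 had the largest difference, 0.76 ± 0.27. No adipocyte gene passed, with GPD1 at 0.83 ± 0.39 and PCK1 at 0.71 ± 0.48. IBSP differed by 1.14 ± 0.41, RUNX2 by −0.23 ± 0.15 and POSTN by −1.16 ± 0.32.

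In DT6 against C 484 genes passed, 365 risen and 119 fallen, with 41.6% of all genes non-overlapping against 33.3% by chance. The count was 127 without C array 1, 236 without C array 2, 317 without DT6 array 2, and 316 and 317 without D2 arrays 1 and 2. Of the 45 named genes that passed, 13 did so whichever array was left out, including BPIFA1, AGR2, LTF, MATN3, GPNMB, PDPN, TCIRG1 and CDH10.

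The comparison of D6 with D2 asks what changed between 2 and 6 weeks without tooth movement. The largest falls were of genes expressed in airway epithelium, and most of the interferon list rose. BPIFA1 fell by 6.48 ± 0.54, AGR2 by 5.44 ± 0.25 (adjusted p = 2.86e-05), TSPAN1 by 4.78 ± 0.26, CLCA1 by 4.73 ± 0.62, MUC13 by 4.51 ± 0.59, the protease inhibitor SLPI by 4.40 ± 0.42, PIGR by 4.38 ± 0.34 and LTF by 4.30 ± 0.38. Of the 49 motile cilium genes 10 fell, or 25 adjusted over the list alone, with a median of −0.51 (adjusted p = 0.00412 with an estimated correlation). Of 27 columnar epithelium genes 1 fell, or 2 adjusted over the list alone, with a median of −0.19 (adjusted p = 0.00112, and adjusted p = 0.425 with an estimated correlation). In the interferon list 13 of 17 genes rose, or 16 adjusted over the list alone, with MX1 at 2.27 ± 0.30, ISG15, a ubiquitin-like protein, at 1.99 ± 0.39, HERC6 at 1.91 ± 0.26 and USP18 at 1.88 ± 0.26. Their median was 1.49 (adjusted p = 1.68e-28, and adjusted p = 0.734 with an estimated correlation).

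Proliferation, osteoclast and matrix lists also passed. No proliferation gene passed in limma over all genes, while 11 of 28 fell and 1 rose adjusted over the list alone, and the list fell with a median of −0.60 (adjusted p = 3.20e-12, and adjusted p = 0.734 with an estimated correlation), or −0.38 without D2 array 1. KIF11 differed by −0.94 ± 0.26 and DLGAP5 by −0.87 ± 0.29. No osteoclast gene passed over all genes, 2 of 16 rose adjusted over the list alone, and the list rose with a median of 0.40 (adjusted p = 3.36e-06, and adjusted p = 0.750 with an estimated correlation). MMP9 differed by 1.29 ± 0.36, SLC9B2 by 1.34 ± 0.37 and ACP5 by 1.00 ± 0.33. TGFB2 rose by 0.85 ± 0.15 and WIF1, a secreted Wnt inhibitor, by 1.15 ± 0.19. TGFB2 was the only one of 22 BMP and TGF-beta genes to pass, or 2 adjusted over the list alone. That list rose (median 0.15, adjusted p = 0.0216, and adjusted p = 0.736 with an estimated correlation), but not without D6 array 2 (median 0.044, adjusted p = 0.283). The fibrillar matrix list fell (median −0.24, adjusted p = 0.00337, and adjusted p = 0.786 with an estimated correlation), but not without D6 array 1 (median −0.12, adjusted p = 0.524). None of its 27 genes passed over all genes and 1 fell adjusted over the list alone, with CTHRC1 at −0.98 ± 0.34 and FAP at −0.86 ± 0.18.

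In D6 against D2 268 genes passed, 34 risen and 234 fallen, with 43.3% of all genes non-overlapping against 33.3% by chance. Without D2 array 1 the count was 145. Of the 23 named genes that passed, 11 did so whichever array was left out, including BPIFA1, AGR2, CLCA1, SLPI and MX1.

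The comparison of DT6 with D6 asks what tooth movement changed at the same time after surgery. The largest rises were of genes expressed in airway epithelium, and most of the interferon list fell, while the bone genes of the key list did not pass. BPIFA1 rose by 6.94 ± 0.54 (122-fold, adjusted p = 0.000427), BPIFB1 by 5.30 ± 0.76, AGR2 by 4.90 ± 0.25, DMBT1 by 4.75 ± 0.56, SCGB1A1 by 4.73 ± 0.61, LTF by 4.67 ± 0.38, PIGR by 4.45 ± 0.34 and TSPAN1 by 4.24 ± 0.26. Of the 49 motile cilium genes 10 rose, or 27 adjusted over the list alone, with a median of 0.57 (adjusted p = 0.00412 with an estimated correlation). None of the 27 columnar epithelium genes passed in limma over all genes, 1 rose adjusted over the list alone, and their median was 0.04 (adjusted p = 0.0542, and adjusted p = 0.542 with an estimated correlation). In the interferon list 15 of 17 genes fell, or 16 adjusted over the list alone. MX1 fell by 2.90 ± 0.30 (adjusted p = 0.00169), USP18 by 2.35 ± 0.26, ISG15 by 2.34 ± 0.39 and OAS1 by 2.16 ± 0.28. The list median was −1.95 (adjusted p = 5.10e-39, and adjusted p = 0.734 with an estimated correlation).

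Adipocyte genes rose in 3 of 16 cases, or 11 adjusted over the list alone: PCK1, which supplies glycerol for triglycerides, by 2.70 ± 0.48, DGAT2 by 2.12 ± 0.38 and the glycerol phosphate dehydrogenase GPD1 by 1.99 ± 0.39. The list median was 0.86 (adjusted p = 1.14e-14, and adjusted p = 0.734 with an estimated correlation), or 0.54 without DT6 array 2. TGFB2 fell by 0.81 ± 0.15. Of the bone genes, RUNX2 differed by 0.12 ± 0.15, ALPL by −0.37 ± 0.33, COL1A1 by −0.28 ± 0.24, SOST by 0.29 ± 0.18, TNFSF11, the osteoclast differentiation factor RANKL, by 0.53 ± 0.37, ACP5 by 0.06 ± 0.33 and MMP9 by 0.08 ± 0.36. A p that misses the threshold does not show that these values were equal.

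Other lists also passed in DT6 against D6. The fibrillar matrix list fell (median −0.27, adjusted p = 0.000291), as did BMP and TGF-beta signalling (median −0.15, adjusted p = 0.043), the monocyte and macrophage list (median −0.20, adjusted p = 0.0256) and proliferation (median −0.23, adjusted p = 0.00998). The oral epithelium list also fell (median −1.38, adjusted p = 0.00318), and complement and coagulation rose (median 0.23, adjusted p = 0.0373). With an estimated correlation the adjusted p was 0.751, 0.736, 0.827, 0.786, 0.854 and 0.786 for these 6. Over all genes only TGFB2 passed among their members, and adjusted over the list alone 1 BMP gene and 1 macrophage gene fell and 1 complement gene rose. TNN differed by −1.19 ± 0.41, C1QC by −0.71 ± 0.17, KIF11 by −0.54 ± 0.26, DSG1 by −3.02 ± 1.51 and F5 by 1.40 ± 0.33. Without D6 array 1 the oral epithelium list passed in the opposite direction (median 0.37, adjusted p = 0.0162), and its adjusted p was 0.0583 without DT6 array 2. The macrophage median was 0.20 without DT6 array 1, and its adjusted p was 0.0997 without D6 array 1. The complement median was −0.18 without DT6 array 2, and its adjusted p was 0.124 without D6 array 2 and 0.0508 without C array 1. The fibrillar matrix call ended without D6 array 2 (median −0.13, adjusted p = 0.2) or DT6 array 2 (median −0.08, adjusted p = 0.229), and the proliferation call without D6 array 2 (adjusted p = 0.0558) or DT6 array 1 (adjusted p = 0.063), and its median was −0.14 without DT6 array 2. The BMP call ended without C array 1 (adjusted p = 0.0504), D6 array 2 (median −0.09, adjusted p = 0.395), DT6 array 1 (adjusted p = 0.0584) or DT6 array 2 (median −0.041, adjusted p = 0.212), and with the replicate number as a block (adjusted p = 0.0519).

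In DT6 against D6 243 genes passed, 210 risen and 33 fallen, with 29% of all genes non-overlapping against 33.3% by chance. Without DT6 array 2 the count was 154. Of the 210 genes that rose, 186 had also risen in D2 against C, a comparison that shares no array with this one, where independent lists would share 11.9. Of the 234 genes that fell in D6 against D2, 184 had risen in DT6 against C, where independent lists would share 5.36. Of the 25 named genes that passed, 18 did so whichever array was left out, including BPIFA1, AGR2, MX1, USP18, HERC6 and IFI44.

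**Figure D3:**
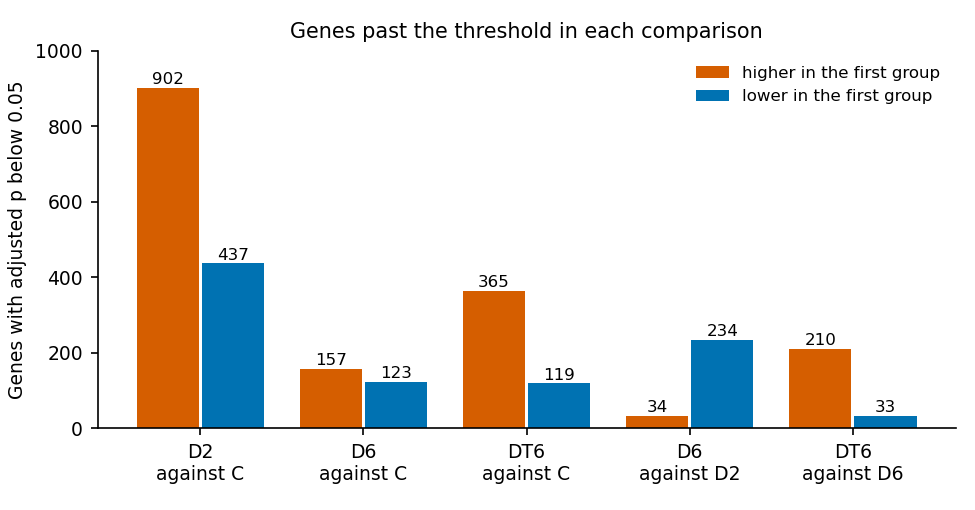
Bars give the number of genes with an adjusted p below 0.05 (vertical axis, from 0) that were higher or lower in the first group of each comparison (horizontal axis). D2 against C has the most, 902 and 437, while rises make up 210 of 243 in DT6 against D6 and falls 234 of 268 in D6 against D2.

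Of the 30 lists, 16 passed in none of the 5 comparisons, with a lowest adjusted p of 0.0583. In D2 against C, the comparison with the most calls, skeletal muscle (median −0.15) and erythroid genes (median −0.11) had no member past the threshold in limma, over all genes or over the list alone, with TNNC2 at −0.58 ± 0.26 and ALAS2 at 1.14 ± 0.38. B cell genes had 1 risen member of 18, BLNK at 1.19 ± 0.26, or 2 adjusted over the list alone. T and NK cell genes had 2 of 22, CD2 and CD4, and granulocyte genes 2 of 18, both also 2 adjusted over the list alone. Inflammatory cytokines and chemokines had 4 of 24, or 5 adjusted over the list alone. Endothelial genes had 1 risen and 4 fallen of 19, pericyte and smooth muscle genes 1 risen of 12, RGS5 at 0.76 ± 0.16, and megakaryocyte and mast cell genes 1 risen and 1 fallen of 11. The FGF, IGF, hedgehog and Notch list had 2 risen and 2 fallen of 20. For these 4 lists the counts adjusted over the list alone were the same. The periodontal ligament and tendon list had 2 risen and 3 fallen of 10, with THBS4 at −1.50 ± 0.27, or 4 and 3 adjusted over the list alone. The osteoclast regulators had 2 risen of 9, SEMA3A at 1.12 ± 0.24 and SEMA4D at 0.75 ± 0.15, or 2 risen and 1 fallen adjusted over the list alone. The tooth list had AMELX fallen and KLK4 risen, at 1.50 ± 0.20, of 9 genes, or 2 risen and 3 fallen adjusted over the list alone. The hypoxia list had ENO1 risen, at 0.72 ± 0.12, of 18, or 1 risen and 4 fallen adjusted over the list alone.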

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

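Of the tests in this part, those of the airway epithelium and of normalization were written before the value they measure was seen, and the test of healing time or tooth movement alone, all tests of the interferon and DMP1 patterns and the counts of probe sets without a gene were chosen afterwards. The change against C in D6 minus that in D2 is D6 against D2 itself, since C cancels, and likewise for DT6 and D6. What follows restates those comparisons, reported above, and is no further test. The change against C differed between D6 and D2 for 268 genes and between DT6 and D6 for 243 genes. Between D6 and D2 the shift differed for the interferon response (median 1.49), proliferation (−0.60), osteoclast (0.40), fibrillar matrix (−0.24) and BMP and TGF-beta lists (0.15). Between DT6 and D6 it differed for the interferon response (−1.95), oral epithelium (−1.38), adipocyte (0.86), fibrillar matrix (−0.27), proliferation (−0.23), complement and coagulation (0.23), monocyte and macrophage (−0.20) and BMP and TGF-beta lists (−0.15). None of these 13 list differences passed with an estimated correlation, where the lowest adjusted p over all 150 tests was 0.734 and 9 had an unadjusted p under 0.05.

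Among the 6163 probe sets without a single gene symbol, which the comparisons did not use, 127 were higher and 203 lower in D2 than in C, 29 higher and 45 lower in D6 than in C, and 79 higher and 82 lower in DT6 than in C, in limma over all 22708 probe sets. Among these comparisons with C the largest rise was 5.72, in DT6, and the largest fall −3.23, in D2. In D6 against D2 12 were higher and 27 lower, with a largest fall of −5.19. DT6 against D6 had 21 higher and 3 lower, with a largest rise of 5.91.

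Genes of airway epithelium were higher in all 4 D2 and DT6 arrays than in all 4 C and D6 arrays. With quantile normalization added, the motile cilium median of DT6 minus D6 was 0.55 against 0.57, 96.5% of its value (95% bootstrap interval 95.9 to 103). This further step could change little, since the deposited arrays already had medians between 6.25 and 6.31. It therefore does not test the normalization behind the deposited values. Healing time alone or tooth movement alone does not account for the pattern. Of the genes that rose in DT6 against D6, 88.6% also rose in D2 against C. The former pair has the same time, and the latter has no tooth movement. Airway epithelium in the D2 and DT6 tissue also stays open, a hypothesis that passed a test it could have failed. Of 49 cilium genes not looked at before, 30, or 61.2%, had this order, and 0 had the opposite. Chance gives 1.43%, while 667 of all 15947 genes had the order. BPIFA1 lay between 11.25 and 12.69 in those arrays, only 4 of 27 columnar epithelium genes had the order, and whether nasal or glandular mucosa could have been cut with the block was not tested.

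Interferon-induced genes were higher in both D6 arrays than in the other 6. More leukocytes in the D6 tissue were tested on the assumption that leukocyte genes would then move as far, which was not itself tested. The lowest bound of the 4 leukocyte list medians of DT6 minus D6 was −0.43, for macrophages, above the interferon interval of −2.05 to −1.37. These intervals measure the spread between list members and not between arrays. With an array left out, the macrophage median ran from −0.68 to 0.20. Oral epithelium in 1 D6 array does not account for the interferon pattern. In D6 array 2, the array without raised keratinocyte genes, 100% of the 17 members were higher than in all 6 arrays outside D6. Healing time alone would leave DT6 level with D6, and the absence of tooth movement alone would leave D2 level with D6, but the list medians were −1.95 for DT6 minus D6 and 1.49 for D6 minus D2, and the interval bound nearest 0 was 1.08 in size. A state of the animals that gave both D6 arrays, such as an infection, cannot be told apart from a joint effect of time and absence of tooth movement, an untested hypothesis, because 0 of the D6 arrays carry an animal in the labels.

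DMP1, an osteocyte and dentin matrix protein, was 6.82 and 11.84 in the D6 arrays and 12.25 and 6.23 in the DT6 arrays. Fewer osteocytes in the arrays with low DMP1 would lower the other osteocyte genes as much, but the upper bound of their median difference was 0.46, against DMP1 differences of 5.01 and 6.02. A fault of the DMP1 probe set was tested by other genes that were over 1 log2 higher with it in both pairs. There were 15, led by MMP20 (3.66 and 2.76), SLC38A11 (3.16 and 2.33) and SEMA3E (3.93 and 1.38), while 1 gene followed in the opposite pairing. Another 25 genes were over 1 log2 lower with it in both pairs, against 2 in the opposite pairing. Over all genes, array 1 minus array 2 of D6 and of DT6 correlated with r = −0.19. Genes can therefore follow this pairing whatever the DMP1 probe set does, and the test cannot exclude a fault. Tooth root tissue in the arrays with high DMP1 cannot be told apart from another source. MMP20, itself a member of the tooth list and higher with DMP1 in both pairs, was left out of this test. The upper bound for the other 8 tooth genes was 0.61 and the lower −0.16, which leaves a shift of 0.5 open. An exchange of labels between a D6 and a DT6 array cannot be told apart either: the pairs alike in DMP1 had an SD of the difference across genes of 0.406 and 0.496, against 0.385 and 0.409 in the labelled pairs, while the interferon list means over C were alike within the labelled pairs, 1.78 and 1.53 in D6 and −0.16 and −0.01 in DT6, as were those of the cilium list, −0.06 and −0.09 in D6 and 0.50 and 0.52 in DT6.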

How the results depend on the processing

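The alternatives without the arrays rich in oral epithelium transcripts and without genes of the airway pattern were chosen after seeing the data; all others were planned. Of the 227 named differences past the threshold, 0 changed direction under any alternative run. With an array left out none could, since the groups of every gene past the threshold did not overlap. Alternatives that change only the estimate of the spread or the threshold could not turn a direction either. Between 193 and 223 stayed past the threshold where all 227 were tested with all arrays, and between 90 and 215 with an array left out, fewest without C array 1. The skeletal muscle list had no member among the upper 50% of genes and gave no value there. Signal over background was not used here, so what depth limits was seen only through the filters on dim genes.

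In the order D2, D6 and DT6 against C, then D6 against D2 and DT6 against D6, the counts of genes past the threshold were 1339, 280, 484, 268 and 243. At an adjusted p of 0.10 they were 2228, 737 and 889 for the first 3, and with a 2-fold minimum 620, 180 and 319, both by construction. In the upper 50% of genes by mean they were 768 (D2 against C), 133 (DT6 against C), 49 and 47, and in the upper 75% 173 and 144 for the last 2. Fewer genes were tested under both filters, but D6 against C still had 240 of 280 in the upper 50%. Testing fewer genes thus need not lower a count that far. How much of the lower counts came from calls among dim genes was not tested. Array weights, equal within a group at 0.782, 1.69, 1.4 and 0.541 for C, D2, D6 and DT6, gave 476 for D6 against C, 176 for DT6 against C and 482 for D6 against D2. A fit of the compared groups alone gave 147 for DT6 against D6. Without both oral epithelium arrays the counts were 534 for D2 against C and 49 for D6 against C, from fewer arrays. Without the genes higher in all D2 and DT6 than in all C and D6 arrays they were 733 (D2 against C), 45 (DT6 against C), 0 (D6 against D2, with 793 at an unadjusted p under 0.05) and 15 (DT6 against D6). Those genes are chosen by the differences then counted, so these counts had to fall and do not measure a dependence on airway tissue. Both groups of D6 against C lie low in that order, and its count without those genes was 296 against 280. For MX1 D6 against D2 still gave 2.27 there, but the adjusted p was 0.0678 and not 0.00486, as fewer small p-values were left to adjust with. Where no reason is given, the cause was not tested.

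Leaving out each array in turn gave 310 to 1940 genes for D2 against C, 0 to 683 for D6 against C, 127 to 719 for DT6 against C, 145 to 315 for D6 against D2 and 154 to 318 for DT6 against D6. The labels do not say whether the replicate numbers pair the arrays. Deviations of same-numbered arrays correlated with r from −0.26 to 0.19. This neither shows nor excludes a pairing, since differences between replicates such as the oral epithelium transcripts enter these deviations too. With the replicate number as a block the counts were 1048, 188, 373, 241 and 208 in the order above and 35 lists passed, where 36 had, and 2 of the 36 list calls ended.

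Of 150 list tests 36 passed. With an estimated correlation 0 passed, with 9 at an unadjusted p under 0.05, and with fry 1 passed, the osteocyte list in D2 against C. With an array left out 32 to 45 passed. Oral epithelium reversed with both oral arrays left out, to −0.36 in D6 against C and 0.37 in DT6 against D6, and over arrays left out in turn ran from −0.36 to 3.69 and from −3.60 to 0.37. The monocyte and macrophage median in DT6 against D6 ran from −0.68 to 0.20 and the complement median from −0.18 to 0.54. Among values that had not passed, the DT6 against D6 difference ran from −0.18 to 1.25 for TNFSF11, −0.98 to 0.25 for ALPL, −0.61 to 0.054 for COL1A1, −0.33 to 0.44 for ACP5 and −0.35 to 0.51 for MMP9. The cause was not tested.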

Other observations

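Of the genes that rose in DT6 against D6, 24 were not among those that rose in D2 against C, which is no test of a difference between the comparisons. They include PCK1, DGAT2 and GPD1 of the adipocyte list. The following ones were picked after their values had been seen. NNAT rose by 1.89 ± 0.36, RBP7, a retinol-binding protein of fat and endothelium, by 1.49 ± 0.25 and PTGER3, a prostaglandin E2 receptor, by 1.19 ± 0.18. The proton pump subunit ATP6V1B1 rose by 1.25 ± 0.16, and the dynein light chain DYNLRB2 by 1.18 ± 0.19 and the kinesin KIF6 by 1.20 ± 0.21. The adipokine ADIPOQ had values of 10.51 and 10.91 in C, 9.23 and 9.40 in D2, 9.44 and 6.74 in D6, and 9.66 and 11.03 in DT6.

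Of the 33 genes that fell in DT6 against D6, 15 belong to the interferon list fixed beforehand. TGFB2 belongs to the BMP and TGF-beta list. Others included RNF213 at −1.92, DHX58 at −1.69, PARP14 at −1.66, BST2 at −1.30, IRF9 at −0.81, TAPBP at −0.88 and FKBP5 at −1.52. These others were also chosen after their values had been seen.

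D2 and DT6, which differ in both time and tooth movement, had 0 genes past the threshold between them in limma, with 992 at an unadjusted p under 0.05 and a lowest adjusted p of 0.106. A count of 0 with 2 arrays per group does not show that they were alike. Over all genes, 667 had all D2 and DT6 arrays above all C and D6 arrays and 334 had the opposite order, where chance gives 228 for each.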
